A study of Mus musculus with 11 samples.

How the data were processed

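RNA was measured on 11 perfect-match probe set arrays: 3 each of the CD4 T cell subsets LG_naive, LG_eTconv and LG_eTreg from the lacrimal glands of 16-week-old male NOD mice, and 1 each of total CD4 (Spl_CD4) and total CD8 (Spl_CD8) T cells from the spleens of the same mice. Per the labels, gland suspensions were made by mechanical dissociation and enzyme digestion, live CD4 and TCRβ positive cells were sorted into lysis buffer, and RNA was isolated with RNAqueous, amplified with NuGEN Ovation and labelled with biotin. The labels give an RNA integrity number above 9.1 for all samples but 1, whose value of 7.8 they do not tie to a group, so no group was assigned to it. The deposited values are log2 signals that the authors made with RMA in Partek, per the submitters' processing notes, which give no versions. The base of the logarithm is inferred: RMA gives log2 values. The steps between spike-in controls do not settle it: from bioB to bioC the step was 1.23, where the nominal concentrations would give 1.74 in log2 and 1.20 in natural logarithms, from bioC to bioD 1.95 (2.32 and 1.61) and from bioD to cre 0.85 (2 and 1.39). Precision is limited by the number of arrays, since array signals give no counts.

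The table held 45141 probe sets, of which 104 controls were left out. Of the other 45037, 28898 had exactly 1 gene symbol, 551 had several and 15588 had no gene listed in the annotation used here. The probe set with the highest mean over the 9 lacrimal gland arrays stood for each gene, which left 17097 genes, 7180 of them with more than 1 probe set. Of the genes named here 0 had probe sets called in opposite directions, but other probe sets of a gene could show a smaller difference or none. No filter on dim genes was used. The background limit of an array was the highest value of its nonspecific control probe sets, which are grouped by GC content, and ran from 0.945 to 1.70 over the arrays. Where all arrays of a group lay at or below their limits, the difference was given as at least N-fold, computed against the limit. List medians were also computed with every value below 1.70 set to that level, which moved them by up to 1.06. They are given as values at the background limit where they differ after rounding.

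The design, tests, gene lists, naming rule and alternative settings were fixed before the data were examined. Genes were tested with limma 3.58.1 in R 4.3.3: a mean per group over the 9 lacrimal gland arrays (6 residual degrees of freedom), moderated by empirical Bayes, with contrasts LG_eTconv minus LG_naive, LG_eTreg minus LG_naive and LG_eTreg minus LG_eTconv. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 17097 genes of its comparison. Differences are on the log2 scale, first group minus second, with a standard error (SE) or group means ± SD. Replicate numbers were not used as pairs, since the labels do not say that they mark the same mice. Spleen comparisons have no test: genes were counted where the log2 difference was at least 1 and all 3 LG_naive arrays lay on the same side of Spl_CD4. Their list medians were placed among 10000 random lists matched on mean level in 20 bins, as a description of these arrays.

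There were 21 gene lists, tested in 3 comparisons (63 tests, adjusted together) with limma camera at a preset inter-gene correlation of 0.01: regulatory T cell signature, follicular helper T cell, T helper 1 and cytotoxic, T helper 2, T helper 17, naive and recirculating T cell, inhibitory receptors and exhaustion, anergy, costimulatory TNF family, proliferation, chemokine receptors with integrins and tissue residence, T cell receptor response with immediate early genes, type I interferon response, glycolysis, cholesterol synthesis, and markers of B and plasma cells, monocytes and macrophages, dendritic cells, CD8 T and natural killer cells, lacrimal gland epithelium, and fibroblasts with endothelium and erythrocytes. Of the 43 calls, 23 held with an estimated correlation, where the smallest adjusted p was 0.00309. Adjusted p-values of lists given below use the preset correlation unless stated. The smallest of them overstate the evidence where the genes of a list are correlated. Genes of the sort gate (Cd4, Pdcd1, Icos, Nt5e, Cd200) were kept apart from the lists. Some list genes had no probe set under their symbol in the annotation used here and are not reported here. Named genes were the 10 largest rises and falls per comparison among called genes without overlap between groups, leaving out gate genes and clone or numbered names, then up to 4 called members of each list with the largest change, and fixed genes such as Foxp3, Il10, Bcl6 and Ifng.

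The method was tested on simulated data in which 100 genes each were shifted by 1 and by 2 on the log2 scale, with each gene's own spread on these arrays: 59%, 49% and 58% of the first and 88%, 86% and 87% of the second were called in the 3 comparisons, with 16, 9 and 5 false calls among 16897 unchanged genes. In the first comparison the 16 false calls stood beside 59 and 88 true ones, a larger share than the adjusted p of 0.05 aims at. Far more genes were called in the data (2303, 1995 and 974) than were shifted here. The cut-off therefore differed, and these shares do not give the recovery in the comparisons themselves. A shifted list was called in each comparison and 0 of 18 other lists were. Genes were simulated as independent of each other, so this does not show how the list test behaves with correlated genes. Alternatives were a filter on dim genes (mean above 1.41, 10210 genes), the mean of a gene's probe sets, all probe sets, array weights, a trend and robust variance prior, only the groups compared, a replicate block, median centring, a repeated quantile normalization, fold thresholds, an estimated correlation and limma's fry for the lists, and each array left out in turn. Leaving out LG_naive 1, LG_eTconv 1 and LG_eTreg 3 together was chosen after seeing the data, because these arrays had the highest 18S signals or the widest actin gap. Further lists of plasmacytoid and myeloid genes and of imprinted genes were also chosen after seeing the data, and their results stand in the closing section. For each comparison of 3 arrays with 3, all 10 splits of the 6 arrays were fitted.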

Results

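Gene expression was measured on 11 arrays of RNA from T cells of 16-week-old male NOD mice, a strain that develops autoimmune inflammation of the lacrimal gland (LG) and serves as a model of Sjögren's syndrome. CD4 T cells of the gland were sorted into 3 subsets with 3 arrays each: LG_naive, without surface PD-1 and ICOS, and LG_eTconv and LG_eTreg, effector conventional and effector regulatory cells, both high for PD-1 and ICOS. Total CD4 and total CD8 T cells from the spleens of the same mice gave 1 array each, named Spl_CD4 and Spl_CD8. All values are on the log2 scale, and the base of the logarithm is inferred. The median over all genes ran from 2.26 to 2.39 on the 11 arrays. Of the 17097 genes tested, the number above each array's background limit ran from 9483 (55.5%) on LG_naive 1 to 11211 (65.6%) on LG_eTreg 2. The number of arrays limits the precision, and since the labels do not say whether replicates came from separate mice or pools, p-values measure only the spread between these samples, which may be technical. The signal of the 18S ribosomal RNA control was 6.76 on LG_eTreg 3 and 6.15 on LG_naive 1, against 3.57 to 5.34 on the others. The gap between the 3′ and 5′ actin controls was widest on LG_eTconv 1, at 3.35, against 1.53 to 2.86 on the others. Correlations across genes, which are not independent replicates, were 0.980 to 0.991 between arrays of a lacrimal gland group and 0.943 to 0.975 between arrays of different groups.

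Pdcd1 and Icos, genes behind the sort gate, separated LG_naive from both effector subsets, and since the cells were sorted on their proteins this is no finding. Pdcd1, which encodes PD-1, stood at 1.83 ± 0.28 (SD, n = 3) in LG_naive, 7.23 ± 0.48 in LG_eTconv and 7.46 ± 0.68 in LG_eTreg. Icos was higher than in LG_naive by 1.06 in LG_eTconv and by 1.22 in LG_eTreg. Between LG_eTreg and LG_eTconv, Pdcd1 differed by 0.23 (adjusted p = 0.857) and Icos by 0.16 (adjusted p = 0.605, or 0.0465 with the mean of its probe sets). The study's design gives the same gate, low for CD73 and for CD200, for both effector subsets. Cd200 was lower in LG_eTreg than in LG_eTconv (log2 difference −1.10, adjusted p = 0.00222), which a gate stated as the same for both does not account for. Nt5e, which encodes CD73, differed by −0.93 (adjusted p = 0.0462), and this call ended with all probe sets tested (0.0683) and without LG_naive 2 (0.0526), LG_naive 3 (0.0588), LG_eTconv 1 (0.0986), LG_eTconv 2 (0.142), LG_eTconv 3 (0.135), LG_eTreg 1 (0.13), LG_eTreg 2 (0.0864) or LG_eTreg 3 (0.0948). Against LG_naive, Nt5e was higher by 4.35 in LG_eTconv and by 3.42 in LG_eTreg, and Cd200 by 3.62 and 2.51. A gate low for CD73 and CD200 does not by itself select for such rises. The 3 probe sets of Nt5e disagreed, with differences down to −0.12 in LG_eTconv and −0.06 in LG_eTreg.

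The comparison of LG_eTconv with LG_naive asks what marks effector conventional CD4 T cells inside the inflamed gland. Il21, a cytokine that helps B cells, was at 8.52 ± 0.16 in LG_eTconv and 1.11 ± 0.20 in LG_naive, where 1 of 3 arrays was above background (log2 difference 7.40, SE 0.14, adjusted p = 3.79e-08). Ifng, the interferon gamma gene, was at 9.37 ± 0.05 against 4.44 ± 0.27 (difference 4.93, SE 0.16, adjusted p = 8.34e-07). Il2, the T cell growth factor, was at 6.53 ± 0.01 against 1.47 ± 0.86, with 1 of 3 LG_naive arrays above background (adjusted p = 7.54e-05). Sostdc1, a secreted antagonist of BMP and Wnt signals, was at 8.95 ± 0.19 and below background in LG_naive, which makes it at least 182-fold higher. In total 1103 genes were higher and 1200 lower in LG_eTconv among 17097 tested (2303 genes, 13.5%), and 1478 of them differed at least 2-fold. In each called gene all 3 values of 1 group lay beyond all 3 of the other, a pattern that 31.1% of all genes showed and that chance gives in 10%.

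Helper and effector programs were both higher in LG_eTconv. Of 19 measured follicular helper T cell genes 10 were higher and 1 lower (11 and 1 adjusted over the list alone), with a median log2 difference of 0.83 (list test adjusted p = 4.88e-08). Beside Il21 and Sostdc1 they included the transcription factor Maf (3.30), the TNF family ligand Tnfsf8 (3.24) and the follicle-homing receptor Cxcr5 (2.35). Bcl6, the transcription factor of follicular helper cells, was higher by 0.57 (adjusted p = 0.0135). Of 19 other settings 3 did not call it, among them the mean of its probe sets (0.21) and the removal of LG_naive 1, LG_eTconv 1 and LG_eTreg 3 together (0.096). Of 24 T helper 1 and cytotoxic genes 15 were higher and 3 lower (17 and 3 adjusted over the list alone; median 1.20, or 1.08 at the background limit; adjusted p = 2.26e-08), among them the chemokine Xcl1 (4.77), the granule protein gene Nkg7 (4.32), the transcription factor Tbx21 (3.68) and the chemokine receptor Cxcr3 (3.34). The T helper 17 list rose by a median of 0.50 (0.22 with values under background set to the limit) through 3 of 7 genes, Ahr (3.19), Ccr6 (2.09) and Rora (1.64) (adjusted p = 0.00576, or 0.0922 with an estimated correlation), while Il17a itself was below background on all arrays. In the T helper 2 list 1 of 9 genes was higher, the transcription factor Gata3 (1.86), and the list did not pass its test (median 0.02, or 0.00 at the background limit, adjusted p = 0.328). Since 7 of the 9 genes were at background on all lacrimal gland arrays, the tests of this list say little about T helper 2 programs in any of the 3 comparisons.

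Genes known from regulatory, inhibited and costimulated T cells were also higher in LG_eTconv. The regulatory T cell signature had 17 of 24 genes higher and none lower (18 and 0 adjusted over the list alone). Its median was 1.76 (adjusted p = 7.85e-17, or 0.00804 with an estimated correlation). The chemokine receptor gene Ccr8 was at least 25.3-fold higher, Tnfrsf9 and Tnfrsf4, which encode 4-1BB and OX40, differed by 4.36 and 4.08, and the cytokine gene Il10 by 3.76. Foxp3, the transcription factor that defines regulatory T cells, differed by 0.29 (SE 0.49, adjusted p = 0.802), and Il2ra, the high-affinity interleukin 2 receptor chain, by 0.55 (adjusted p = 0.0564, or 0.049 without LG_naive 2 or without LG_eTconv 3). Of 14 costimulatory TNF family genes 10 were higher and none lower (10 and 1 adjusted over the list alone; median 1.38, adjusted p = 1.94e-09). Tnfsf11, the gene of RANK ligand, was up by 3.85. In the inhibitory receptor list 6 of 13 genes were higher and 1 lower (7 and 2 adjusted over the list alone), led by Lag3 (3.75), with a median of 0.66 (adjusted p = 0.000237, or 0.0602 with an estimated correlation). The anergy list had 7 of 17 genes higher and 2 lower (8 and 5 adjusted over the list alone; median 0.21, adjusted p = 0.00774, or 0.0569 with an estimated correlation). The ubiquitin ligase gene Rnf128 was up by 3.85. Of 26 genes of the T cell receptor response 9 were higher and 3 lower (12 and 5 adjusted over the list alone; median 0.30, adjusted p = 0.00445, or 0.304 with an estimated correlation), and the transcription factor Bhlhe40 (2.88) was among the higher ones.

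Cell cycle and glycolysis genes were higher too. Of 29 proliferation genes 12 were higher and none lower (15 and 0 adjusted over the list alone; median 0.95, or 0.59 at the background limit; adjusted p = 6.42e-08, or 0.107 with an estimated correlation). The nuclear antigen gene Mki67, above background on 2 of 3 LG_naive arrays, differed by 3.39 (SE 0.62, adjusted p = 0.00731) and the spindle gene Nusap1 was at least 7.21-fold higher. Of 14 glycolysis genes 6 were higher and 1 lower (7 and 1 adjusted over the list alone; median 0.46, adjusted p = 0.000448), with Tpi1 (2.67) and Hk2 (1.94) as examples. Among chemokine receptors, integrins and residence genes 8 of 20 were higher and 4 lower (11 and 4 adjusted over the list alone; median 0.48, or 0.44 at the background limit; adjusted p = 0.000643). The chemokine receptor gene Ccr2 was at least 4.72-fold lower. Of the 10 largest rises, several belonged to no list: Penk, the enkephalin precursor, by 6.53 (1 of 3 LG_naive arrays above background), Nts, the neurotensin precursor, at least 45.0-fold, Ccn4, a matrix signalling protein, at least 78.1-fold, and the collagen gene Col24a1 at least 49.2-fold.

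Genes of naive T cells were lower in LG_eTconv. Of 17 naive and recirculating T cell genes 13 were lower and 1 higher (14 and 1 adjusted over the list alone). Their median was −3.31, or −2.75 at the background limit (adjusted p = 5.03e-14, or 0.00309 with an estimated correlation). Igfbp4 stood at 3.09 ± 0.19 against 7.70 ± 0.11 in LG_naive (difference −4.60, SE 0.23, adjusted p = 5.60e-06), the chemokine receptor gene Ccr9 differed by −4.15, and the transcription factor gene Sox4 was at least 12.3-fold lower. Ramp1 was the member that was higher, by 1.73 (adjusted p = 0.0455, up to 0.132 with 1 array left out); it was chosen after its values were seen. Of 20 type I interferon response genes 10 were lower and 1 higher (11 and 2 adjusted over the list alone; median −0.49, adjusted p = 0.00131, or 0.109 with an estimated correlation), as with Oasl1 (−3.02; 1 of 3 LG_eTconv arrays above background) and Ifit2 (−2.14). Cholesterol synthesis genes had 3 of 13 lower (3 adjusted over the list alone; median −0.62, or −0.47 at the background limit; adjusted p = 0.0107, or 0.0602 with an estimated correlation).

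Markers of other cells were lower in LG_eTconv together with these genes. Of 15 monocyte and macrophage markers 7 were lower (11 adjusted over the list alone; median −0.92, or −0.47 at the background limit; adjusted p = 4.63e-07), with the adaptor gene Tyrobp at 4.49 ± 0.30 against 8.07 ± 0.26. Of 12 dendritic cell markers 7 were lower (7 lower and 1 higher adjusted over the list alone; median −1.60, or −0.55 at the background limit; adjusted p = 0.00085, or 0.0602 with an estimated correlation). The MHC class II gene H2-Aa was among them (−2.18). Klra17 and Lair1, inhibitory receptor genes among the 10 largest falls, differed by −4.94 and −5.09. Lacrimal gland epithelium markers had 6 of 19 lower (9 adjusted over the list alone; median −0.95, adjusted p = 6.99e-05, or 0.0602 with an estimated correlation). The adhesion gene Cdh1 differed by −3.52 (2 of 3 LG_eTconv arrays above background). The fibroblast, endothelium and erythrocyte list had 2 of 15 lower (4 adjusted over the list alone; median −0.55, or −0.10 at the background limit; adjusted p = 0.0155, or 0.148 with an estimated correlation, 0.104 without dim genes and 0.0503 without LG_eTconv 3). B cell and plasma cell markers had 1 of 13 lower (median −0.14, or −0.06 at the background limit; adjusted p = 0.328). CD8 T cell and natural killer cell markers had 2 higher and 2 lower of 10 (median −0.11, or 0.00 at the background limit; adjusted p = 0.675). The higher ones were Cd8a, by 1.56 (SE 0.22, adjusted p = 0.00161), and Klrc1, by 1.18 (adjusted p = 0.00808), while Cd8b1 stood at 1.53 ± 0.31.

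**Figure D1:**
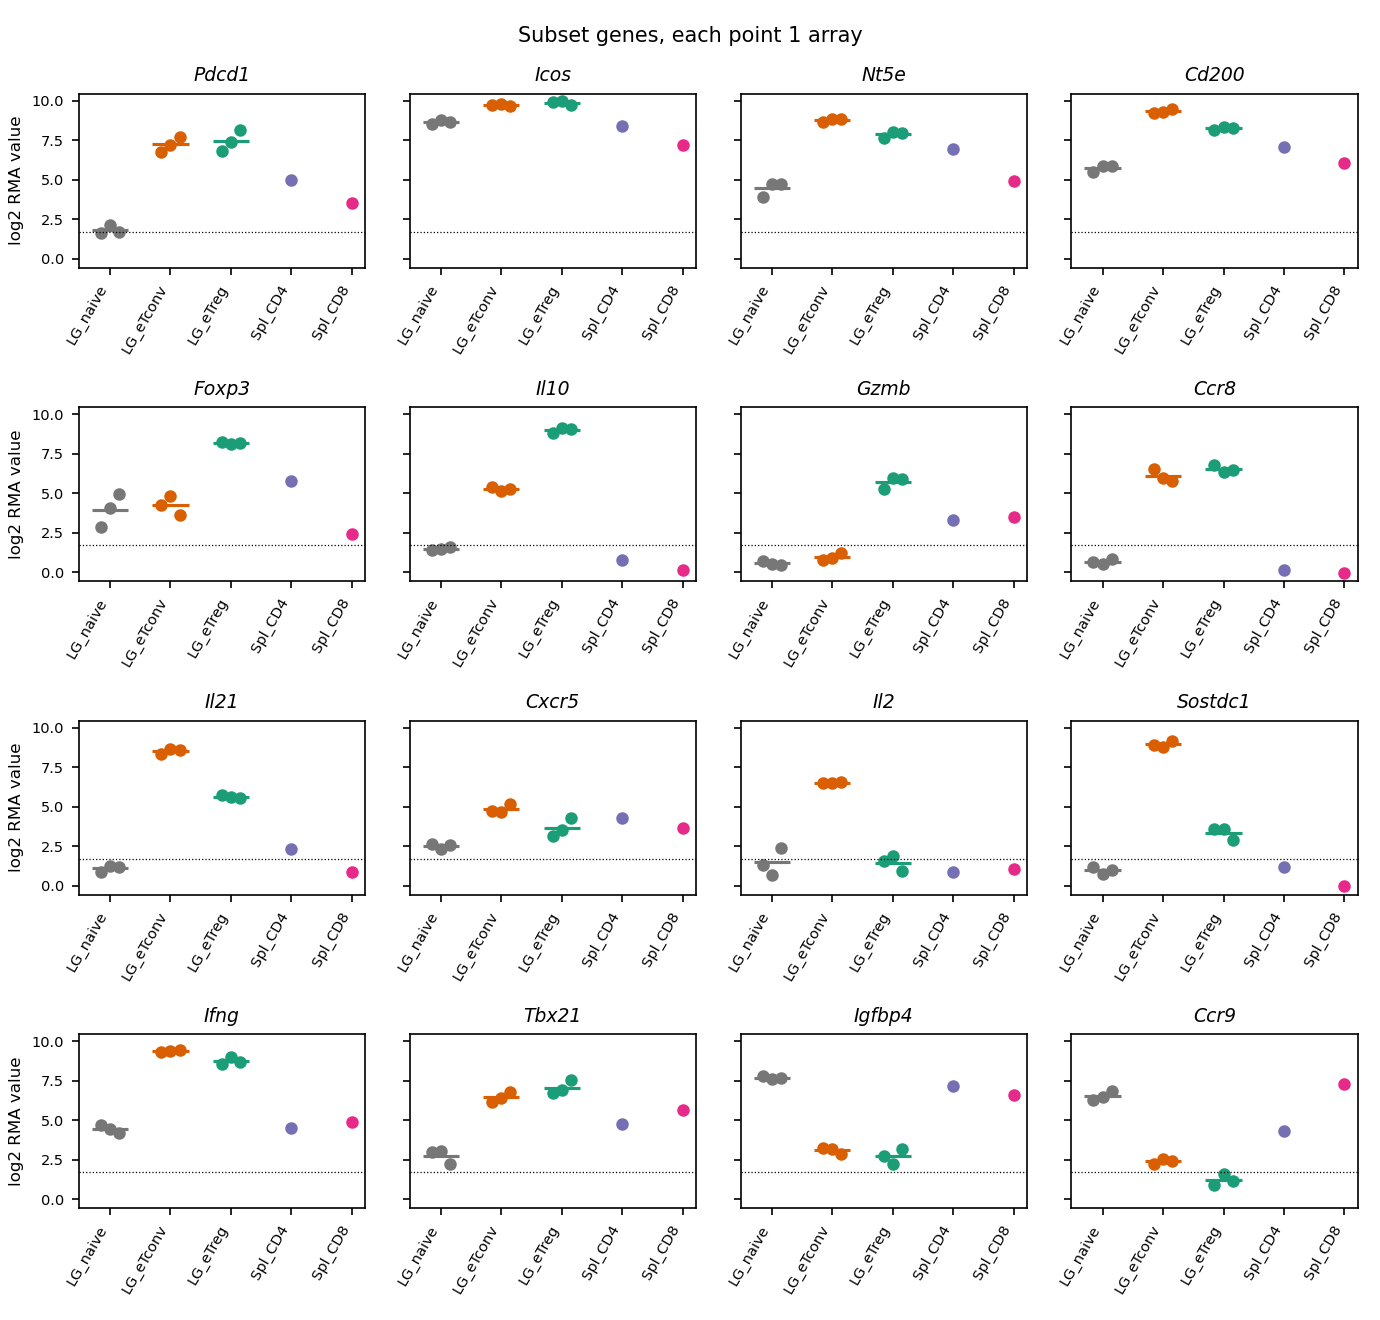
Log2 values (vertical axis) of 16 genes on each of the 11 arrays, by group (horizontal axis); points are arrays, bars are group means and the dotted line is the highest background limit, 1.70. Foxp3 averages 8.18 in LG_eTreg against 4.24 in LG_eTconv, and Il2 averages 6.53 in LG_eTconv against 1.46 in LG_eTreg.

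The comparison of LG_eTreg with LG_naive asks what marks effector regulatory T cells in the gland. Foxp3 was at 8.18 ± 0.05 in LG_eTreg and 3.95 ± 1.04 in LG_naive (difference 4.23, SE 0.49, adjusted p = 0.000752). Il10 was at 8.98 ± 0.17 against 1.49 ± 0.11, with 2 of 3 LG_naive arrays above background (difference 7.49, SE 0.12, adjusted p = 4.66e-08). Of 24 signature genes 23 were higher and none lower (24 and 0 adjusted over the list alone). Their median was 3.44 (adjusted p = 3.01e-38, or 0.00309 with an estimated correlation). Ccr8 was at least 34.5-fold higher, Itgae, which encodes the epithelium-binding integrin CD103, differed by 5.39, the transcription factor Prdm1 by 3.78, Ikzf2, which encodes Helios, by 3.72, and Il2ra by 2.58. In total 1060 genes were higher and 935 lower (1995 genes, 11.7%), 1288 of them by at least 2-fold, and 27.1% of all genes had groups that did not overlap against the 10% that chance gives.

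LG_eTreg also carried T helper 1, chemotactic and inhibitory genes. Of 24 T helper 1 and cytotoxic genes 12 were higher and none lower (15 and 1 adjusted over the list alone; median 1.39, or 1.36 at the background limit; adjusted p = 2.49e-11), with Nkg7 (4.79), Cxcr6 (4.43), Tbx21 (4.31) and Ifng (4.31). Among chemokine receptors, integrins and residence genes 12 of 20 were higher and 1 lower (13 and 1 adjusted over the list alone; median 0.88, or 0.80 at the background limit; adjusted p = 4.88e-08). Cxcr3 differed by 4.12. The inhibitory receptor list had 7 of 13 higher and 1 lower (8 and 2 adjusted over the list alone; median 1.63, adjusted p = 4.95e-07), with Lag3 (4.04) and the ectonucleotidase gene Entpd1 (2.43). In the anergy list 6 of 17 were higher and 2 lower (6 and 3 adjusted over the list alone; median 0.22, adjusted p = 0.00108). In the costimulatory TNF family 7 of 14 were higher and 2 lower (7 and 2 adjusted over the list alone; median 0.80, or 0.68 at the background limit; adjusted p = 6.99e-05), with Tnfrsf9 up by 5.31 and Cd40lg, the CD40 ligand gene, at −2.24. The T helper 17 list had 4 of 7 higher (4 adjusted over the list alone; median 0.74, or 0.11 at the background limit; adjusted p = 0.00125, or 0.0602 with an estimated correlation). The 4 were Ahr (3.67), Rora (2.68), Ccr6 (0.74) and Il17a, which was below background on all arrays (adjusted p = 0.0254, up to 0.0713 with 1 array left out and 0.14 without LG_naive 1, LG_eTconv 1 and LG_eTreg 3 together). In the T helper 2 list, with 7 of 9 genes at background on all lacrimal gland arrays, 1 was higher, the chemokine receptor gene Ccr4, at least 2.14-fold. Its list median was 0.01, or 0.00 at the background limit (list test adjusted p = 0.496).

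Follicular helper genes went both ways: 4 of 19 were higher and 4 lower (4 and 5 adjusted over the list alone). Their median was −0.02, or 0.00 at the background limit, with a mean of 0.30 and a list test adjusted p of 0.865. With fry, which tests the list by itself and not against other genes, the adjusted p was 0.00104. Il21 was at 5.62 ± 0.10 in LG_eTreg (difference 4.50), while Bcl6 differed by 0.11 (adjusted p = 0.692). Sostdc1 was at least 3.76-fold higher on the probe set used, but its other probe set, also above background, differed by 0.07. Proliferation genes were higher in 16 of 29 and lower in none (19 and 0 adjusted over the list alone; median 1.21, or 0.78 at the background limit; adjusted p = 4.65e-11, or 0.0624 with an estimated correlation), with Mki67 at 4.27 (SE 0.62, adjusted p = 0.00258) and the survivin gene Birc5 at 3.99 (2 and 1 of 3 LG_naive arrays above background). Of 20 interferon response genes 8 were higher and none lower (9 and 0 adjusted over the list alone; median 0.43, adjusted p = 0.000171, or 0.0707 with an estimated correlation), with the antiviral genes Mx1 (2.49) and Rsad2 (1.79). Glycolysis genes were higher in 4 of 14 (5 adjusted over the list alone; median 0.35, adjusted p = 0.000636), with the lactate transporter gene Slc16a3 at 3.57 (1 of 3 LG_naive arrays above background). The T cell receptor response list, with 5 higher and 2 lower of 26, did not pass its test (median 0.06, adjusted p = 0.0933). Nor did cholesterol synthesis, with 1 higher and 1 lower of 13 (median 0.19, or 0.22 at the background limit; adjusted p = 0.557). Penk (5.48), Ccn4 (at least 33.3-fold) and the semaphorin gene Sema6d (at least 39.2-fold) were among the 10 largest rises.

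Naive T cell genes were lower in LG_eTreg in 16 of 17 and higher in none (16 and 1 adjusted over the list alone). Their median was −3.27, or −3.12 at the background limit (adjusted p = 1.07e-19, or 0.00309 with an estimated correlation). Ccr9, above background on 1 of 3 LG_eTreg arrays, differed by −5.30, Igfbp4 by −4.99 and Tdrp by −5.90. With them fell B cell markers, in 7 of 13 (7 adjusted over the list alone; median −1.29, adjusted p = 3.38e-05), such as the adaptor gene Blnk, at least 9.70-fold lower. Monocyte and macrophage markers were lower in 5 of 15 (9 adjusted over the list alone; median −0.97, or −0.43 at the background limit; adjusted p = 1e-05), with Tyrobp at −3.75. Dendritic cell markers were lower in 7 of 12 (7 adjusted over the list alone; median −1.49, or −0.69 at the background limit; adjusted p = 0.000721, or 0.0602 with an estimated correlation), with H2-Aa at −2.25. The member that was higher, Zbtb46, by 1.27 (adjusted p = 0.0341, up to 0.116 with 1 array left out), was chosen after its values were seen. Epithelium markers were lower in 3 of 19 (3 adjusted over the list alone; median −0.80, or −0.41 at the background limit; adjusted p = 0.00321, or 0.13 with an estimated correlation), with Cdh1 at −2.77. The fibroblast, endothelium and erythrocyte list was lower in 3 of 15 (4 adjusted over the list alone; median −0.40, or −0.14 at the background limit; adjusted p = 0.0107, or 0.13 with an estimated correlation and 0.0545 without dim genes). The endothelial and leukocyte adhesion gene Pecam1 differed by −3.01. CD8 and natural killer cell markers had 1 higher and 2 lower of 10 (median −0.02, or 0.00 at the background limit; adjusted p = 0.367), with the killer cell receptor gene Klrd1 at −3.56.

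The comparison of LG_eTreg with LG_eTconv asks how regulatory and conventional effector cells of the same gland differ. Foxp3 was higher in LG_eTreg by 3.94 (SE 0.49, adjusted p = 0.00207) and Il10 by 3.73 (SE 0.12, adjusted p = 2.13e-06). Gzmb, the granzyme B gene, was at 5.71 ± 0.39 in LG_eTreg and 0.96 ± 0.22 in LG_eTconv, where 1 of 3 arrays was above background (adjusted p = 6.68e-06). Il2 was at 1.46 ± 0.48 in LG_eTreg against 6.53 ± 0.01 in LG_eTconv (adjusted p = 0.000156). Il21 was at 5.62 ± 0.10 against 8.52 ± 0.16 (adjusted p = 9.96e-06). In total 502 genes were higher and 472 lower in LG_eTreg (974 genes, 5.70%), 655 of them by at least 2-fold, and 21.5% of all genes had groups that did not overlap against the 10% that chance gives.

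The regulatory signature was higher in LG_eTreg, with 12 of 24 genes higher and none lower (18 and 1 adjusted over the list alone). Its median was 1.03 (adjusted p = 1.88e-16, or 0.00804 with an estimated correlation). Itgae (4.21), the secreted suppressor gene Fgl2 (3.86), Prdm1 (3.52) and Il2ra (2.03) were among the higher genes. Ikzf2 differed by 1.02 (adjusted p = 0.096, or 0.0311 without LG_naive 1, LG_eTconv 1 and LG_eTreg 3 together) and Ctla4 by 0.29 (adjusted p = 0.267). The follicular helper list was lower in LG_eTreg, with 10 of 19 genes lower and none higher (13 and 0 adjusted over the list alone). Its median was −1.20 (adjusted p = 2.11e-13, or 0.00309 with an estimated correlation). Among the lower genes were Sostdc1 (−5.60), Tnfsf8 (−3.89, 2 of 3 LG_eTreg arrays above background), Slamf6 (−2.13) and Cd40lg (−2.12). Bcl6 differed by −0.46 (adjusted p = 0.0652; 0.0281 to 0.216 under 19 other settings, 16 of which did not call it). Interferon response genes were higher in 15 of 20 and lower in none (15 and 0 adjusted over the list alone). Their median was 1.11 (adjusted p = 2.39e-17, or 0.0068 with an estimated correlation), with Oasl1 (2.73), Ifit3 (2.37) and Ifit2 (1.92). Ifit1bl1, a relative of the last pair outside the list, was higher by 4.01. Cholesterol synthesis genes were higher in 2 of 13 (5 adjusted over the list alone; median 0.59, or 0.43 at the background limit; adjusted p = 0.000224).

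Effector genes were split between the subsets. In the T helper 1 and cytotoxic list 6 of 24 were higher and 6 lower in LG_eTreg (7 and 7 adjusted over the list alone; median 0.45, or 0.39 at the background limit; adjusted p = 0.156): the chemokine gene Ccl5 (2.91) and Cxcr6 (2.19) were higher and Xcl1 (−3.67) lower. Tbx21 differed by 0.62 (adjusted p = 0.374), Cxcr3 by 0.78 (adjusted p = 0.340) and Ifng by −0.62 (adjusted p = 0.0627; 0.0358 to 0.183 under 19 other settings, 14 of which did not call it). In the costimulatory TNF family 3 of 14 were higher and 6 lower (4 and 7 adjusted over the list alone; median −0.21, or −0.22 at the background limit; adjusted p = 0.109), with the death receptor 3 gene Tnfrsf25 at −2.34. Naive T cell genes had 6 of 17 lower and 1 higher (7 and 1 adjusted over the list alone; median −0.12, adjusted p = 0.00622, or 0.0533 with an estimated correlation), with the transcription factor gene Bach2 at −3.13. The chromatin organiser gene Satb1 differed by 1.51. The inhibitory receptor list had 4 of 13 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.00263, or 0.101 with an estimated correlation and 0.101 without the 3 arrays named above). The TIM-3 gene Havcr2 was higher by 3.15 (2 of 3 LG_eTconv arrays above background), while Lag3 differed by 0.28 (adjusted p = 0.679). The chemokine receptor and residence list, with 6 higher and 4 lower of 20, had a median of 0.43, or 0.27 at the background limit, and an adjusted p of 0.0548, which ran from 3.53e-05 to 0.277 under 15 other settings, 12 of which did not call it. Ccr2 was at least 9.47-fold higher and Ccr6 was lower (−1.35).

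In the T cell receptor response list 2 of 26 genes were higher and 3 lower in LG_eTreg, Il2 among the lower ones. That list had a median of −0.21 and an adjusted p of 0.0537, which ran from 0.00243 to 0.467 under 15 other settings. Since 7 of the 15 did not call it, it stays undecided. Proliferation genes had 1 of 29 higher (0 adjusted over the list alone; median 0.22, adjusted p = 0.0126), and that call ended with an estimated correlation (adjusted p = 0.423), with fry (0.189), without dim genes (0.0719), with array weights (0.112), without LG_eTconv 1 (0.69) and without the 3 arrays named above, where the test turned its direction (0.969). Mki67 differed by 0.88 (adjusted p = 0.598). B cell markers were lower in 3 of 13 (6 adjusted over the list alone; median −0.85, or −0.52 at the background limit; adjusted p = 1.43e-05), such as Cd22 (−1.57). Epithelium markers had 2 of 19 higher (2 adjusted over the list alone; median 0.19, adjusted p = 0.0427, or 0.277 with an estimated correlation, 0.0505 without dim genes, 0.142 without LG_eTconv 3, 0.118 without LG_eTreg 2 and 0.066 without the 3 arrays), Epcam by 3.06. No call was made for the lists of T helper 2 (adjusted p = 0.711, median −0.05, or 0.00 at the background limit, mean 0.01) or T helper 17 (0.675, median 0.48, or 0.24 at the background limit). Anergy had no call either (0.939, median 0.22, or 0.05 at the background limit, mean −0.04). Nor was one made for glycolysis (0.448, median −0.03, mean 0.02, direction of the test down). The same held for monocyte (0.156, median 0.19, or 0.00 at the background limit) and dendritic cell markers (0.653, median 0.09, or 0.00 at the limit). Without LG_eTconv 1 the monocyte list had an adjusted p of 0.0393. CD8 and natural killer cell markers were not called (0.238, median −0.13, or −0.01 at the limit), but had an adjusted p of 0.0295 without dim genes and 0.00277 with fry. Fibroblast, endothelium and erythrocyte markers were not called either (0.675, median 0.05, or 0.00 at the limit, mean −0.09). Differences outside the lists included those of Sytl2 (5.15) and Nxpe4 (4.96), each above background on 1 of 3 LG_eTconv arrays, and Lilrb4a (4.68), higher in LG_eTreg. Lower were Stfa3 (−7.37), Nts (at least 52.4-fold lower) and Twist2 (at least 25.8-fold lower).

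**Figure D2:**
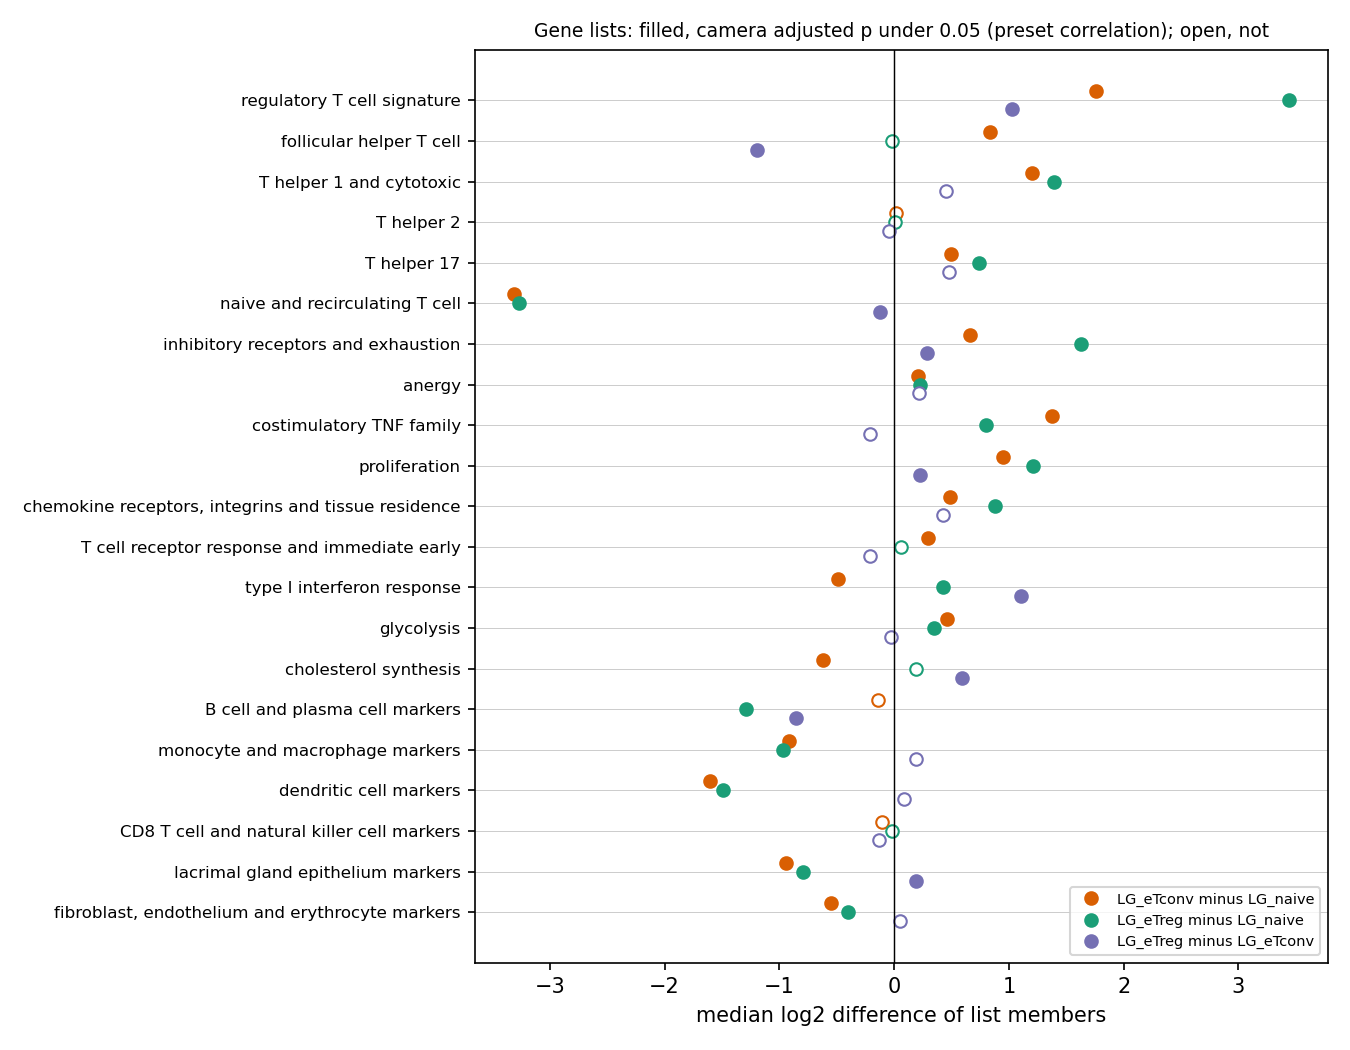
Median log2 difference of the members (horizontal axis) of 21 gene lists (vertical axis) in the 3 lacrimal gland comparisons, by colour; a filled point has an adjusted p under 0.05 with the preset correlation, an open point does not. The regulatory T cell list lies at 1.76, 3.44 and 1.03, and the interferon list at −0.49 in LG_eTconv and 0.43 in LG_eTreg, each minus LG_naive.

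Whether the effector subsets share a program was asked by overlapping their comparisons with LG_naive. Of the called genes, 600 were higher in both and 650 lower in both (1250), where independent lists of these sizes would share 68.4 and 65.6. These included Il10, Ccr8, Tnfrsf9, Tbx21, Ifng, Lag3 and Mki67 among the higher genes and Igfbp4, Ccr9 and Tyrobp among the lower ones. For genes such as Tyrobp and Ccr9 the closing section leaves RNA of other cells in the LG_naive sort open. Such RNA would lower genes in both comparisons without a shared program, so part of the 650 lower genes may reflect it. Between LG_eTreg and LG_eTconv 189 of the 1250 genes were called different and 1061 were not. Another 42 genes were called in opposite directions. The comparisons share the 3 LG_naive arrays, which raises agreement between them: in 20 simulations of unchanged groups against shared controls the log2 differences correlated across genes at 0.50 on average with 0 genes called in both, against 0.73 here. Since the simulated groups did not differ, few genes could be called at all, so that 0 is no reference for the 1250 genes. The covariance was 0.450, against 0.037 in the simulations. With 3 LG_naive arrays the controls could not be divided into separate sets of at least 2 each, so part of the overlap may come from the shared arrays.

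The comparison of LG_naive with Spl_CD4 sets T cells of the gland beside the splenic control. It has no p-value, because there is 1 spleen array, and it also spans 2 tissues, preparations and cell mixtures. Transcripts of the gland epithelium were among the largest differences. Obp1a, an odorant-binding protein gene of glands, was at 9.42 ± 0.19 in LG_naive and 1.70 in Spl_CD4, Ltf, the lactoferrin gene, at 7.72 ± 0.57 against 1.29, and 12 of 19 epithelium markers were at least 2-fold higher and none lower (median 2.37, percentile 100 of 10000 random lists matched on level). Immediate early genes were higher as well, with Fos at 9.57 ± 0.09 against 3.22, Fosb at 8.34 ± 0.10 against 1.51 and the orphan receptor gene Nr4a2 at 6.97 ± 0.21 against 1.86. Of the 26 genes in that list 20 were at least 2-fold higher and none lower (median 1.997, percentile 100). In total 1579 of 17097 genes differed at least 2-fold with all 3 LG_naive arrays on the same side, 798 higher and 781 lower.

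Interferon response genes were higher in LG_naive than in Spl_CD4 in 12 of 20 (median 1.17, percentile 100), such as Usp18 (2.27). So were 5 of 13 genes of the inhibitory receptor and exhaustion list (median 0.73, percentile 100). They included Ctla4 (2.74), but also Nr4a2 (5.11), Nr4a1 (4.35) and Nr4a3 (3.26), which the immediate early list holds as well. The rises of these lists are therefore not separate results. The naive T cell list was higher in 3 of 17 (median 0.40, percentile 99.9), namely the surface marker gene Ly6c1 (3.57), Ccr9 and Sox4. The plasmacytoid and myeloid list of the closing section was also higher in LG_naive than in Spl_CD4 (median 1.21). The dendritic cell list was not (median −0.22). Whether the rises of Ly6c1, Ccr9 and Sox4 come from naive T cells or from other cells in the sort was not tested. B cell markers were lower in 9 of 13 (median −2.57, percentile 0), for instance the CD20 gene Ms4a1 at −3.53. Proliferation genes were lower in 11 of 29 (median −0.59, percentile 0), with Mki67 at −2.86. The regulatory T cell signature was lower in 12 of 24 and higher in 1 (median −1.005, percentile 0). The neutrophil genes S100a9 and S100a8 were at 6.70 and 5.22 in Spl_CD4 and at 0.42 and 0.24 in LG_naive. The haemoglobin gene Hba-a1 differed by −4.81.

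The comparison of the spleen arrays with each other checks the labels and has no replicates. Spl_CD8 was higher for Cd8a (9.35 against 4.45) and Cd8b1 (6.43 against 1.63), the chains of the CD8 coreceptor, and lower for Cd4 (2.47 against 8.49). The natural killer receptor gene Klrc1 (4.60), the transcription factor gene Eomes (4.35) and the granzyme genes Gzmk (3.46) and Gzma (3.30) were higher. Foxp3 (−3.38) and Ctla4 (−3.30) were lower, and Maf was at 0.76, below background, against 4.63. CD8 and natural killer cell markers were at least 2-fold higher in 5 of 10 (median 1.48, percentile 100), T helper 1 and cytotoxic genes were higher in 9 of 24 and lower in 2 (median 0.56, percentile 100). The regulatory T cell signature was lower in 11 of 24 and higher in 2 (median −0.75, percentile 0). Follicular helper genes were lower in 7 of 19 (median −0.52, percentile 0). B cell markers were higher in 2 of 13 (median 0.78, percentile 99.99). In total 641 genes were at least 2-fold higher and 769 lower (1410).

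**Figure D3:**
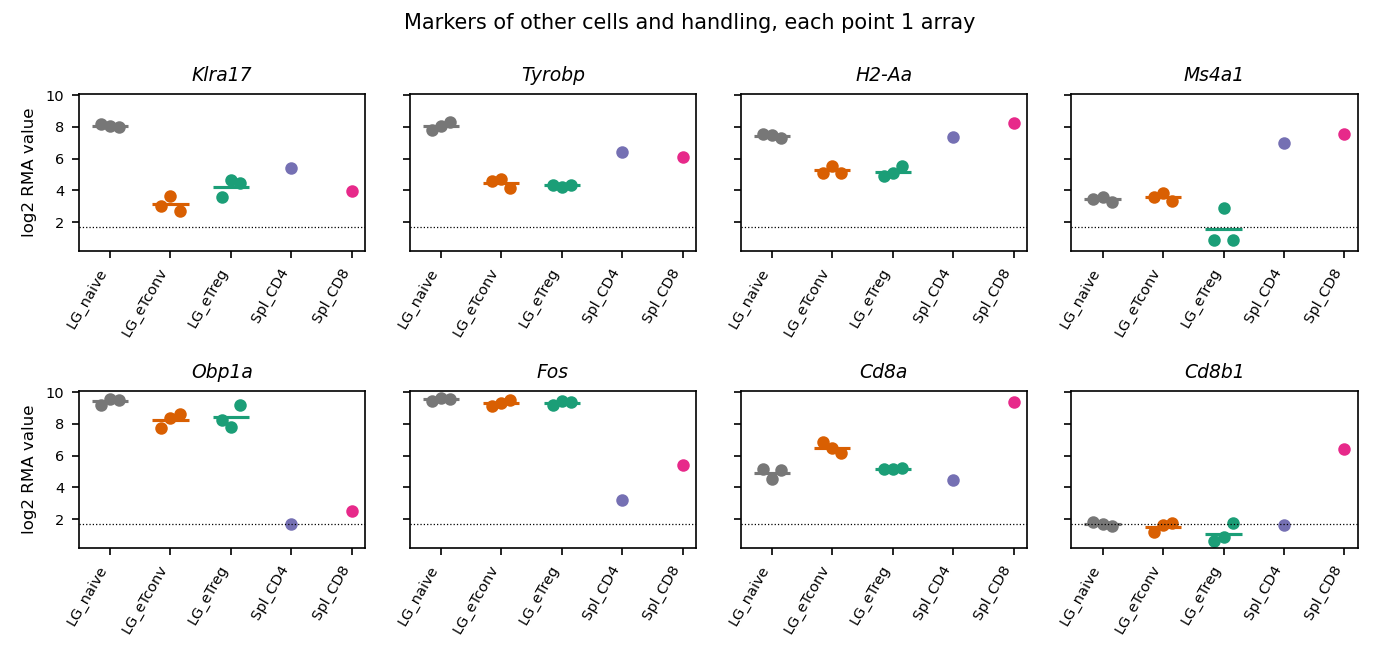
Log2 values (vertical axis) of 8 genes on each of the 11 arrays, by group (horizontal axis); points are arrays, bars are means of groups with 3 arrays and the dotted line is the highest background limit, 1.70. Obp1a lies between 7.76 and 9.59 on the 9 lacrimal gland arrays and at 1.70 and 2.55 on the spleen arrays, and Tyrobp averages 8.07 in LG_naive against 4.49 in LG_eTconv.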

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

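The tests of B cells, CD8 T cells, Cd8a-positive dendritic cells and Cd8a probe sets, of the slope on epithelium markers and of tissue dissociation were chosen after the results had been seen, as were the exact p-values, the rank correlation and the 2 arrays left out beside the epithelium correlation. Probe sets with no gene listed in the annotation used here took no part in the comparisons. Of these 15588, 1013 changed between LG_eTconv and LG_naive (534 higher, 479 lower), 890 between LG_eTreg and LG_naive (488 higher, 402 lower) and 368 between LG_eTreg and LG_eTconv (175 higher, 193 lower). These are 6.50%, 5.71% and 2.36%, against 10.5%, 8.60% and 4.04% of the probe sets with 1 symbol, and their median level was 0.859 against 1.85.

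The counts of called genes were set against the 10 splits of the 6 arrays of each comparison, which are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real grouping, gave as many genes as it did: 2303 for LG_eTconv minus LG_naive, where the highest other split gave 0, 1995 for LG_eTreg minus LG_naive, where it gave 0, and 974 for LG_eTreg minus LG_eTconv, where it gave 1.

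Transcripts of dendritic and myeloid cells were higher in LG_naive than in both effector subsets. B cells in the LG_naive sort as the whole source are argued against by the B cell list, whose median differed by −0.14 between LG_eTconv and LG_naive (−0.06 at the background limit), where the dendritic list differed by −1.60 (−0.55), while for LG_eTreg the values of −1.29 (−1.29) and −1.49 (−0.69) leave a part open. A list of 25 further plasmacytoid and myeloid genes, written before their values were seen, had a median of −1.53 over its 18 measured members in LG_eTconv and −2.33 in LG_eTreg (−1.53 and −2.06 at the background limit), below all of 10000 random lists, with 13 and 14 members called lower, which is consistent with dendritic cells or their RNA in the LG_naive sort. Of these, Mpeg1 and Grn stood in LG_naive at 8.71 and 8.02, although a gate on CD4 and TCRβ would remove such cells, and 12 of the 18 members were also above background on all LG_eTconv arrays while 0 belonged to another fixed list. Expression of these genes by the LG_naive T cells themselves, a difference that the design names, was not tested and stays open. Ly6c1, Ccr9 and Sox4 of the naive T cell list were also lower in both effector subsets. Whether they share a source with the plasmacytoid and myeloid genes was not tested.

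Cd8a was higher in LG_eTconv than in LG_naive by 1.56 (SE 0.22) without Cd8b1. Against CD8 T cells in the LG_eTconv sort, the rise would need a share of 9.65% and a Cd8b1 level of 3.49 if such cells resembled Spl_CD8, while Cd8b1 stood at 1.53 (SD 0.31), and 7 of the 9 genes that mark Spl_CD8, Cd8b1 included, lay below their implied levels, Cryz and Trpm1 not. For dendritic cells that carry Cd8a, the dendritic list was lower in LG_eTconv than in LG_naive (median −1.60, or −0.55 at the background limit). This cannot exclude them, because LG_naive itself had more dendritic transcripts. Between LG_eTreg and LG_eTconv, Cd8a differed by −1.31, while 0 of 12 dendritic markers were called (median 0.09). There, no excess of dendritic transcripts went with Cd8a. A fault of 1 probe set cannot be told apart from a real rise: the other Cd8a probe set above background differed by 1.19 (SE 0.55, adjusted p = 0.278 over all probe sets), and its spread keeps this open. A rise of Cd8a in effector conventional CD4 T cells, a subset that the design names, was not tested further and stays open.

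Immediate early genes were at least 2-fold higher in LG_naive than in Spl_CD4 in 20 of 26 cases. Against RNA of gland epithelium as the whole of the difference, these 20 genes had medians of 0.27 in LG_eTconv and 0.16 in LG_eTreg, each minus LG_naive. The epithelium list fell there (−0.95, and −0.80 or −0.41 at the background limit). Between arrays of a group the 20 genes changed with a slope of 0.215 (SE 0.101) on the 13 epithelium markers above background. A common source would give a slope near 1 only with markers measured without error and signals not compressed. The slope alone therefore does not settle how much of the difference epithelium RNA explains. A part of it may come from such RNA: over the 9 lacrimal gland arrays the deviations from group means correlated at r = 0.692 (exact p = 0.0278 over 216 orderings within groups; Spearman's rho 0.683, exact p = 0.0602; r = 0.562 without LG_naive 2 and LG_eTconv 1, which lay farthest out), and the markers Wfdc18 and Obp1a stood at 9.52 and 9.42 in LG_naive although a gate on CD4 and TCRβ would remove epithelial cells. Both deviations were negative on all arrays numbered 1 and positive on all arrays numbered 2. An effect shared by arrays of the same number would therefore also give this correlation. The exact p-values order arrays freely within groups and do not allow for it, so the correlation does not settle the source. Enzymatic and mechanical dissociation of the gland cannot be told apart from a difference between the tissues, since 18 of the 20 genes were at least 2-fold above Spl_CD4 in all 3 subsets and no spleen array was prepared in the same way. Activation of T cells inside the gland, a tissue difference that the design names, was not tested and stays open.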

How the results depend on the processing

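The removal of LG_naive 1, LG_eTconv 1 and LG_eTreg 3 together was chosen after the data were seen. Requiring a 2-fold difference as well, which can only remove genes, left 1478 called genes for LG_eTconv minus LG_naive and 1288 for LG_eTreg minus LG_naive. Testing all probe sets, which counts a gene more than 1 time, gave 4103, 3424 and 1557 in the 3 lacrimal gland comparisons, 3931 for LG_naive minus Spl_CD4 and 3858 for Spl_CD8 minus Spl_CD4. At least 4-fold differences numbered 407 and 263 in the spleen comparisons. A limma fit over all 11 arrays, in which the lone spleen array is assumed to vary like the lacrimal gland groups, called 663 genes for LG_naive minus Spl_CD4. Counts under all other settings stayed within 1.5 times those reported. With each array left out they ran from 1770 to 2414, from 1512 to 1845 and from 683 to 969 in the lacrimal gland comparisons, from 995 to 1210 for the genes shared by both effector subsets and from 1614 to 1712 for LG_naive minus Spl_CD4. Without the 3 arrays they were 1968, 1617 and 672, and 1597, 1305 and 532 of these were among the genes called with all arrays. The proliferation list in LG_eTreg minus LG_eTconv then turned the direction of its test, with a median of 0.01354 (adjusted p = 0.969), and the cause was not tested. An estimated correlation ended 20 of the 43 list calls. A filter on dim genes ended 4 and gained 1, and array weights ended 1 and gained 1. With fry, which tests a list by itself and not against other genes, 1 ended and 9 were gained. The CD8 and natural killer cell list was gained in all 3 comparisons (adjusted p = 0.000647, 0.000184 and 0.00277). In LG_eTreg minus LG_naive the follicular helper (0.00104), T helper 2 (0.00934) and T cell receptor response lists (0.0465) were gained. In LG_eTreg minus LG_eTconv the T helper 1 (0.00437), costimulatory TNF (0.00149) and chemokine receptor lists (3.53e-05) were. Leaving out the 3 arrays ended 2 list calls beside that of the proliferation list and gained 1. Of the results of named genes, 16 calls ended with only the groups compared, 12 with the mean of probe sets, where 1 was gained, 11 with all probe sets, 4 with array weights, where 2 were gained, 3 with median centring and 32 without the 3 arrays, where 2 were gained. Among 2466 results of named genes with 1 array left out, 186 calls ended and 5 were gained, and among 567 list results 4 ended and 8 were gained. With the replicate number as a block 2271, 1929 and 906 genes were called and 11 named-gene calls ended; of the lists, that of the T cell receptor response in LG_eTreg minus LG_eTconv was gained (adjusted p = 0.0477). The deviations of same-numbered arrays 1, 2 and 3 correlated across genes at −0.05, 0.07 and 0.00 between LG_naive and LG_eTconv, at −0.10, 0.14 and −0.04 between LG_naive and LG_eTreg and at 0.28, 0.08 and 0.17 between LG_eTconv and LG_eTreg. In the last pair of groups every array correlated best with its own number, and among genes with a mean above 3 the correlations were 0.40, 0.12 and 0.23. This hints, from the data and not the design, that these 2 groups may be paired. In the other pairs of groups only array 2 did. Signal over background limits the fold of dim genes, which was given as a bound where all arrays of a group lay at or below their limits.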

Other observations

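The genes described in the next paragraph and the test of imprinted genes were chosen after values had been seen.

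Of the 42 genes called in opposite directions in the effector subsets against LG_naive, 16 were higher in LG_eTconv and lower in LG_eTreg and 26 the reverse; all 42 were also called between LG_eTreg and LG_eTconv, and 20 kept both calls with any 1 array left out. Myh10, a nonmuscle myosin gene, was at 3.88 in LG_naive, 7.48 in LG_eTconv and 2.60 in LG_eTreg (differences from LG_naive 3.59, adjusted p = 2.90e-05, and −1.28, adjusted p = 0.0101). The ADP-ribosyltransferase family gene Art3 stood at 2.19, 5.75 and 0.90, below background in LG_eTreg (adjusted p = 1.32e-05 and 0.00456), and the cyclophilin gene Ppic at 4.61, 6.31 and 2.45 (1.70 and −2.16). Tespa1, which acts in T cell receptor signalling, was at 6.54, 7.30 and 5.34 (0.76 and −1.20). In the other direction, Ppp1r3b, which targets a phosphatase to glycogen, was at 4.64, 1.81 and 5.50 (−2.83 and 0.86). Smad3, a transducer of TGF-β signals, was at 7.86, 7.05 and 8.61 (−0.81, adjusted p = 0.00517, and 0.75, adjusted p = 0.00907), and the adhesion molecule gene Icam1 at 7.60, 6.93 and 8.47 (−0.67 and 0.86). These 7 genes all belong to the 20 that kept both calls with any 1 array left out. In each, as in every called gene, all 3 values of each group lay beyond those of the other. Since the 7 were picked after values had been seen, neither trait is separate support.

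Imprinted genes may change together between LG_eTreg and LG_eTconv, a hypothesis that came from seeing the imprinted noncoding RNA gene Rian among the differences. Of 26 measured imprinted genes 6 were called (Fisher's exact test, two-sided, p = 0.0029 for the whole list), and without the 4 members whose values had been seen 4 of 22 were (18.2%, against 5.67% of other genes; exact p = 0.0335). Without Meg3 and Mirg as well, which lie beside Rian in the genome, 2 of 20 were called (exact p = 0.315), so the result did not hold without that locus and stays undecided. Rian, Meg3 and Grb10 were higher in LG_eTconv than in LG_naive and lower in LG_eTreg than in LG_eTconv. Rian was at 1.08 in LG_naive, 6.40 in LG_eTconv and 1.89 in LG_eTreg, Meg3 at 0.97, 4.53 and 0.66, with LG_naive and LG_eTreg below background, and Grb10 at 1.80, 5.51 and 1.59. Mirg was below background on all 9 arrays, and Rasgrf1 was at 2.71 in LG_eTreg and below background in the other groups. Ascl2 differed by −1.78 and kept its call in 7 of the 9 fits with 1 array left out (adjusted p up to 0.0519).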
